A study of Mus musculus with 3 samples.

How the data were processed

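The series holds single-cell RNA sequencing of mouse kidney in 3 libraries. They are 1 unsorted library from mice given a control antibody, 1 unsorted library from mice given an antibody against CSF1R, and 1 library of CD11b-sorted cells from mice given the antibody against CSF1R. Per the labels, libraries were made with the 10x Chromium 3' chemistry, version 3.1, and the submitters' processing notes name Cell Ranger 3.1.0. The authors deposited, for each library, a filtered matrix of raw counts, that is, the number of unique molecular identifiers (UMIs) per gene and barcode. The values were whole numbers with no normalization, and every barcode had at least 500 UMIs. The genome build and the gene annotation are not given in the sources used here. Cell names were not used from any source: all cell types below were named anew from marker genes and are written with the ending "-like".

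The control library held 9002 barcodes and 56501293 UMIs, the anti-CSF1R library 9941 barcodes and 64020565 UMIs, and the CD11b-sorted library 8492 barcodes and 60785926 UMIs. The median number of UMIs per barcode was 4870, 5183 and 4625, and the median number of genes was 1764, 1743 and 1762. The gene tables of both unsorted libraries were identical (32285 genes), and that of the CD11b-sorted library differed (31053 genes). The clustering and the ratios between the sorted and the unsorted library used the 30406 genes shared by Ensembl identifier, which left out 1879 genes of the unsorted tables and 647 of the sorted one. Any pair of libraries shared at most 24 barcode sequences.

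Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 25% mitochondrial UMIs. The gene minimum removed 270, 7 and 22 barcodes and the mitochondrial maximum was exceeded by 1049, 80 and 60 barcodes of the control, anti-CSF1R and CD11b-sorted libraries. The median mitochondrial share was 3.88%, 2.60% and 1.30%. Doublets were scored with Scrublet in Scanpy for each library, and the highest scores were removed at a nominal rate of 0.8% per 1000 barcodes. This took 629, 790 and 575 of the scored barcodes, some of which had also failed the mitochondrial maximum. The automatic Scrublet threshold would have called 333, 476 and 358. After all filters 7360, 9076 and 7851 cells were kept. Free RNA in the droplets was not subtracted. It was measured instead as the UMIs of 10 abundant tubule genes in T cell-like cells, and genes that could be free RNA in a class were left out of the genes named by size.

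All libraries were clustered together with no batch integration. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within libraries without mitochondrial, ribosomal, haemoglobin and sex-linked genes. Then 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 33 clusters. Each cluster took the name of the class, out of 24 with fixed marker genes, whose markers were on average highest in it over the other clusters, among classes with at least 3 markers detected. A cluster stayed unnamed if its 10 leading genes held more markers of another class, or held none while it had few UMIs or markers of a further class. This named 15 classes and left 4 clusters unnamed, with 281, 159 and 279 cells (3.82%, 1.75% and 3.55% of kept cells). The largest unnamed cluster had a median of 1166 UMIs and detected 5 macrophage markers, and it held 210 cells of the control library, 71 of the anti-CSF1R library and 260 of the CD11b-sorted library. The others were a cycling cluster led by Pclaf, Top2a and Birc5 (30, 88 and 14 cells), a tubule cluster of 28 control cells, and a cluster led by Upk3a with 13 control and 5 sorted cells. Interferon-induced genes led a monocyte-like cluster (Ifi211, Ifi205, Ifi204), a T cell-like cluster (Cxcl10, Ifit1, Isg15) and a B cell-like cluster (Ifit3b, Ifit3).

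The unsorted libraries were compared with each other, and the CD11b-sorted library with the unsorted anti-CSF1R library, in cell shares and, for each class with at least 100 cells in both libraries, in expression. With 1 library per group no test of a difference between groups was possible and no p-values were computed. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and the limit given for a share of 0 is 3 counts of the total. UMIs were summed over the cells of a class and expressed as counts per 1000000 UMIs (CPM), and ratios carry exact conditional binomial 95% intervals. A gene with no UMI in one library was given a bound computed from 3 counts. Where a class is compared with the other classes, the median was taken over classes in which the gene had at least 20 UMIs and 20% of the CPM of the class in question. That form of the comparison was chosen after seeing the data, since a first form took lymphocytes that held little more than free RNA as the reference.

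The cell filters, the clustering, the marker genes, the 28 gene lists and the rule for named genes were set before the data were examined; the step from markers to names was not among them. The gene rule took genes with at least 50 summed UMIs and a UMI in at least 10% of cells in the library where they were higher. It left out mitochondrial, ribosomal, haemoglobin and predicted genes and genes under 20% of the CPM of the class where they were highest. The 12 highest and 12 lowest ratios were named in macrophage-like cells and the 5 highest and 5 lowest in the other classes, with up to 4 members of each described list and 11 genes of fixed interest. Some genes that these rules chose are not reported here. A list is described by the median log2 ratio of its measured members (at least 50 summed UMIs), by its percentile among 10000 random lists matched on mean expression, and by the number of members at least 1.5 times higher or lower. The percentile describes these libraries and is no test across mice. Of the resident macrophage list, 9 members were also macrophage markers used for naming, so their presence in that class is by definition.

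The interval and list procedures were tested on simulated data, with counts drawn at the depth of the macrophage-like comparison from its pooled gene means. Summed counts were drawn from Poisson distributions, the model that the intervals assume, with no variation between cells or mice. The simulation therefore checks the computation, and not whether the intervals cover the variation in these libraries. Changes were put into 200 genes, and 5323 genes were measured. The 95% intervals held the true ratio for 95.2% of unchanged genes, 97.6% of genes changed 2-fold and 96.6% of genes changed 4-fold. Of 200 random lists, 4.5% fell outside the central 95%, and a list of doubled genes reached the 100th percentile.

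Alternatives were Leiden resolutions of 0.5 and 2, mitochondrial maxima of 10% and 50%, a minimum of 1000 UMIs, no doublet removal, the automatic doublet threshold, clustering each library on its own, median of ratios scaling, the mean of CPM per cell, cells thinned to 2000 UMIs, and minima of 20 and 200 summed UMIs. Reading the low-UMI cluster as macrophage-like, list medians relative to the other classes or without possible free RNA, the alternatives for the shares of other classes and those for the sorted against the unsorted library were added after seeing the data. Lists were described in a class only where their values were also computed under these alternatives, and the other lists and classes were not analysed further here. Ratios within single clusters of a class were also added after seeing the data, for clusters with at least 100 cells in both libraries. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, and cells with fewer were left out.

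All computations were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and Matplotlib 3.10.9.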

Results

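Single-cell transcriptomes were collected from kidneys of C57BL/6 mice, an inbred laboratory strain, that had been given an antibody against CSF1R or an isotype control antibody at 8 weeks of age. CSF1R is the receptor for the growth factors CSF1 and IL-34, on which most tissue macrophages depend. Kidneys were taken 6 weeks after the injection and digested to single cells, and cells that excluded DAPI, a DNA dye that enters dead cells, were sorted. There were 3 libraries: control antibody, anti-CSF1R, and anti-CSF1R cells sorted further for CD11b, an integrin chain of myeloid cells and of many natural killer cells. The labels speak of 3 mice per treatment, and the files do not assign cells to single mice. Each group was therefore 1 library with no replicate, no spread between replicates could be checked, and all intervals are 95% intervals for counting error only. The control library had 56501293 UMIs and 7360 kept cells, the anti-CSF1R library 64020565 UMIs and 9076 kept cells, and the CD11b-sorted library 60785926 UMIs and 7851 kept cells.

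The first comparison asked which cell types the kidneys held 6 weeks after the antibody, in a series described as one of mice depleted of kidney-resident macrophages. Macrophage-like cells, which carry complement C1q genes, Adgre1 and Csf1r, made up 9.32% of immune cells in the control library (8.62 to 10.1%, 601 cells) and 2.65% in the anti-CSF1R library (2.32 to 3.01%, 231 cells). The ratio of these shares was 0.284 (0.243 to 0.331), or 0.348 without doublet removal. Among all kept cells the shares were 8.17% and 2.55%, with a ratio of 0.312 (0.267 to 0.363). Monocyte-like cells, the circulating precursors of many tissue macrophages, were more frequent in the anti-CSF1R library, at 9.85% of immune cells against 6.99% (ratio 1.41, 1.26 to 1.58). Natural killer cell-like cells, cytotoxic innate lymphocytes, were also more frequent, at 16.1% against 12.6% (ratio 1.28, 1.18 to 1.40). Both ratios depended on the processing. The monocyte-like ratio was 1.24 with at least 1000 UMIs and 1.18 with each library clustered on its own. The natural killer cell-like ratio was 1.1 with a mitochondrial maximum of 10%.

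The other immune classes with at least 100 cells differed less in share. B cell-like cells made up 28.3% of immune cells in the control library and 30.7% in the anti-CSF1R library (ratio 1.08, 1.02 to 1.15). They lay mostly in different clusters, with 1403 of 1826 control cells in one and 2238 of 2682 anti-CSF1R cells in another, both led by Fcer2a and Ighd. T cell-like cells made up 35.0% and 34.1%, and their ratio of 0.976 had an interval that included 1 (0.923 to 1.03). The ratio was 1.04 with a mitochondrial maximum of 10%. The share of type 2 conventional dendritic cell-like cells, which present antigen to T cells, had a ratio of 1.05 (0.833 to 1.32), or 0.785 with each library clustered on its own, where 57 anti-CSF1R cells and no control cell of the class were named type 1. Innate lymphoid cell-like cells had a ratio of 1.1 (0.880 to 1.38). Neutrophil-like cells, short-lived phagocytes, were less frequent in the anti-CSF1R library (ratio 0.492, 0.318 to 0.755), from 38 cells against 57. Plasma cell-like cells numbered 54 against 75 (ratio 0.532, 0.368 to 0.765), basophil-like or mast cell-like cells 30 against 57 (0.389, 0.241 to 0.615) and plasmacytoid dendritic cell-like cells 60 against 49 (0.905, 0.610 to 1.35). Unnamed clusters held 3.82% of control cells and 1.75% of anti-CSF1R cells.

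**Figure D1:**
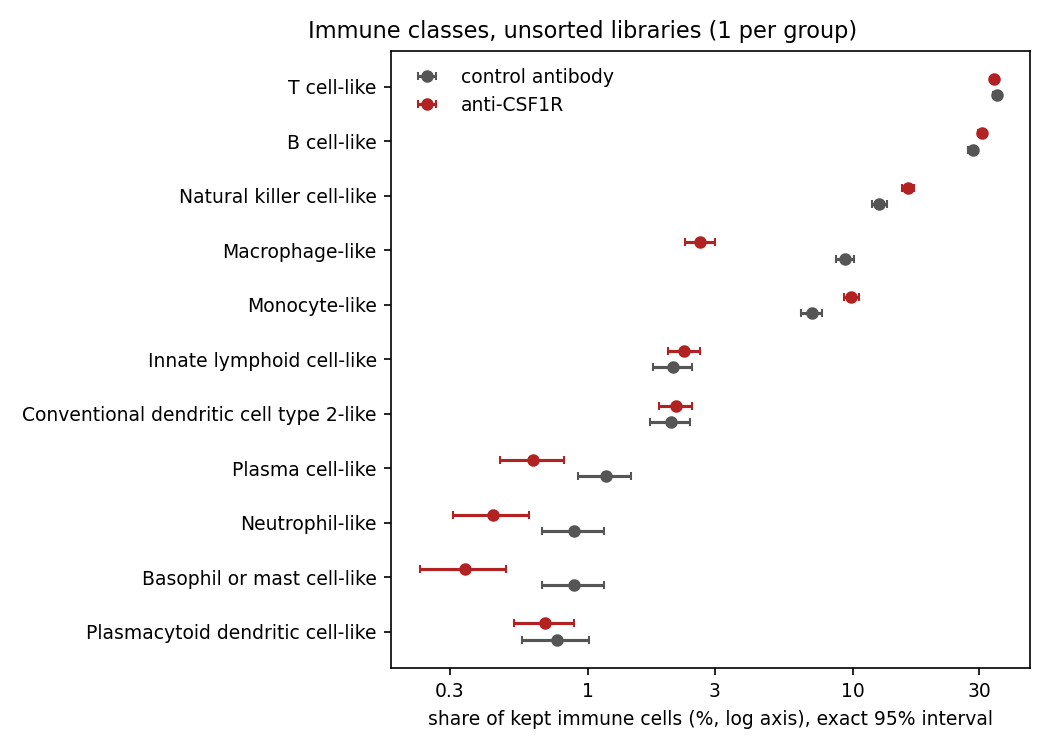
Share of kept immune cells by class (percent, log axis) in the unsorted control library (grey) and the unsorted anti-CSF1R library (red), as points with exact 95% binomial intervals. The macrophage-like share was 9.32% in the control library and 2.65% in the anti-CSF1R library, while the T cell-like shares were 35.0% and 34.1%.

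Kidney epithelial cells were found nearly only in the control library. Cells of the thick limb of the loop of Henle, which reabsorbs salt, numbered 344 in the control library (4.67% of kept cells) and 8 in the anti-CSF1R library (0.0881%), a ratio of 0.0189 (0.00808 to 0.0376), or 0.0584 with a mitochondrial maximum of 10%. Proximal tubule-like cells, which reabsorb most of the filtrate, numbered 203 and 1 (ratio 0.00399). Endothelial cell-like cells, which line vessels, went the other way, with 5 cells in the control library and 170 in the anti-CSF1R library (ratio 27.6, 11.6 to 86.0). That ratio was 5.31 without doublet removal and 4.78 with the automatic doublet threshold. Podocyte-like cells of the glomerulus numbered 79 and 9, with medians of 1391 and 7529 UMIs per cell, so the cells were unlike in depth. Their ratio of 0.0924 lay above 1 under 5 of the alternatives, up to 6.27 with each library clustered on its own. Immune classes together made up 87.6% of control and 96.2% of anti-CSF1R cells. The labels call both unsorted libraries immune cells and describe only a DAPI-negative sort, so the gate that would remove tubule cells is not known. Free tubule RNA in T cell-like cells was 688 counts per 1000000 UMIs (CPM) in the control library and 1.31 in the anti-CSF1R library.

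Within macrophage-like cells, the question was how the cells present 6 weeks after the antibody differed in expression from those of control kidneys. Ccr2 (ENSMUSG00000049103), the chemokine receptor by which monocytes leave the bone marrow and enter tissue, was 1.99 times as high in the anti-CSF1R library, at 778 against 390 CPM (log2 ratio 1.00, 0.88 to 1.11). In the other classes with enough Ccr2 the median log2 ratio was -0.26. Stab1 (ENSMUSG00000042286), a scavenger receptor of tissue macrophages, was lower (log2 ratio -2.17, -2.66 to -1.71), with 42 UMIs against 392. Macrophage identity genes were lower by less: Csf1r itself had a log2 ratio of -0.49 (-0.60 to -0.38), Adgre1, the F4/80 antigen, -0.59 (-0.74 to -0.44), and Cx3cr1, the fractalkine receptor, -0.20 (-0.30 to -0.11). Heat-shock genes and the cytokine gene Il1b were higher.

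These values rest on 1511070 UMIs of 231 anti-CSF1R cells and 3134751 UMIs of 601 control cells, with medians of 5929 and 4985 UMIs per cell. The median log2 ratio over all 5492 measured genes was -0.14, and median of ratios scaling moved every value by only -0.01. Of the genes that met the size minimum, 536 were left out of the named genes as possible free RNA, and 387 of these were lower in the anti-CSF1R library.

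The 12 genes with the highest ratios included 5 chaperone genes of the heat-shock response. They were Hsp90aa1 (log2 ratio 2.03, 1.92 to 2.14), Dnajb1 (2.02, 1.80 to 2.25), Hsph1 (1.89, 1.44 to 2.35), Hspa1b (1.67, 1.59 to 1.76) and Hspa1a (1.57, 1.51 to 1.64). In the other classes with enough of each gene, the medians for Hspa1a and Hspa1b were 1.69 and 1.79. Those for Hsp90aa1, Dnajb1 and Hsph1 were 0.79, 1.08 and 0.63. Hspa1a plus Hspa1b, compared in every class, had a log2 ratio of 1.61 in macrophage-like cells. It was 1.48 in monocyte-like and 1.91 in type 2 dendritic cell-like cells, and higher in lymphoid classes, at 2.63 to 2.91. Ifrd1, a transcriptional coregulator, had the highest ratio (2.48, 2.15 to 2.82), with a median of 1.86 in the other classes. Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, had a log2 ratio of 2.05 (1.72 to 2.39). The remaining genes were Olfm1 (1.91), Clec4n, which encodes the fungal receptor dectin-2 (1.65), Tnip3, an inhibitor of NF-kB signalling (1.63), the guanylate-binding protein gene Gbp8 (1.56), and the transporter gene Abcg3 (1.46). Their summed counts were 53 to 84 UMIs in the anti-CSF1R library. Olfm1 was also among the 10 leading genes of the type 2 dendritic cell-like cluster, and admixture was not tested for it.

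Among the 12 genes with the lowest ratios, the chemokine gene Cxcl14 stood at -4.11 (-6.00 to -2.72), with 4 UMIs in the anti-CSF1R library and 143 in the control library. Dlc1 had 0 and 74 UMIs, a log2 ratio of at most -3.57. Serpinb6a, a serine protease inhibitor gene, stood at -3.53 (-5.18 to -2.27), against a median of 0.06 in the other classes. Further genes were Cdr2 (-2.85), Xlr (-2.60), Leng8 (-2.51), the glycosyltransferase gene B3galnt1 (-2.51), the membrane protein gene Pmp22 (-2.16), the metalloprotease gene Adam33 (-2.16), the RNA-binding protein gene Igf2bp3 (-2.12) and Zgpat (-1.71). Leng8 was lower in the other classes too, with a median of -1.02, and Cdr2 was higher there, with a median of 1.28. The size rule chose 7 of these 24 genes again with cells thinned to 2000 UMIs, and 7 with a minimum of 200 summed UMIs.

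**Figure D2:**
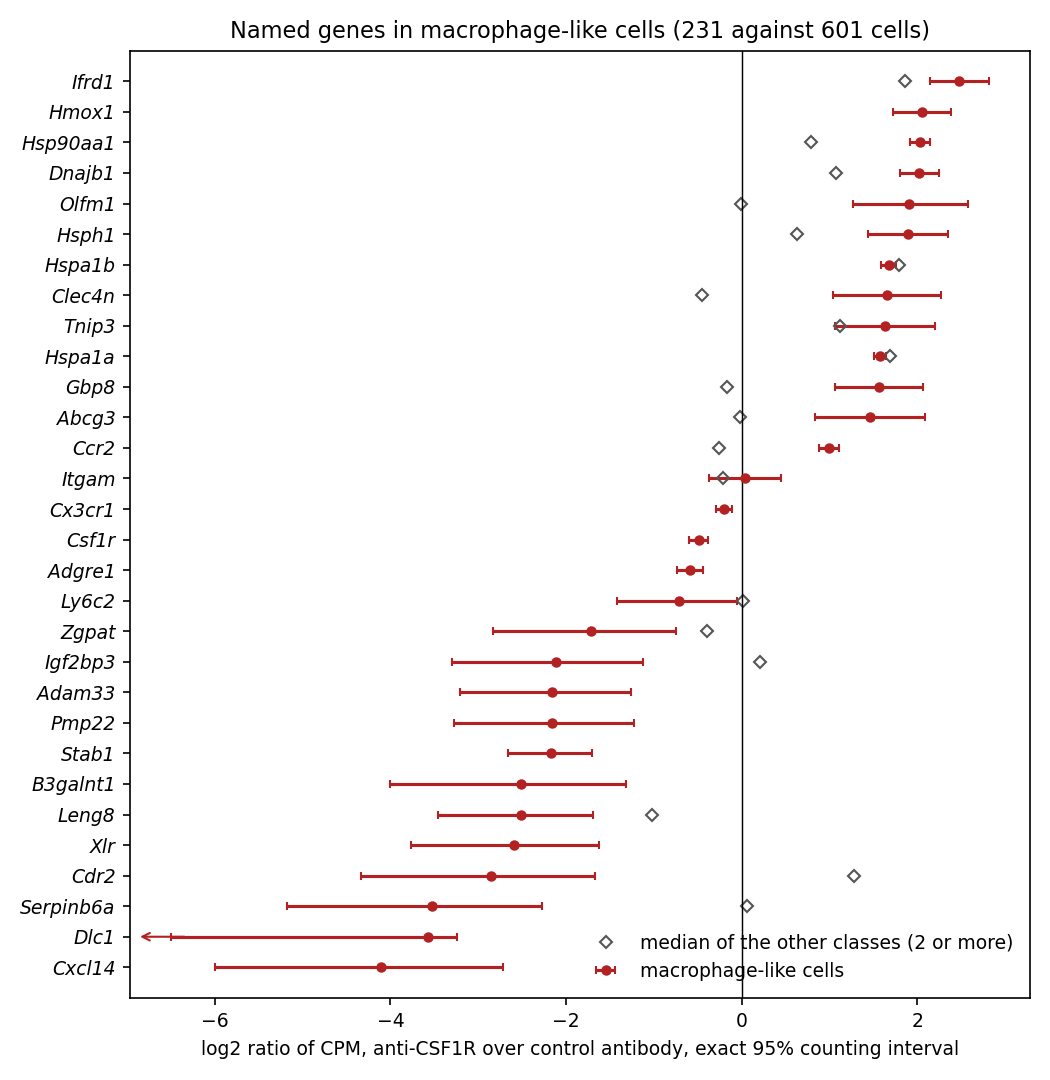
Log2 ratio of CPM in macrophage-like cells, anti-CSF1R over control antibody, for the 24 genes chosen by size and the fixed genes with enough UMIs, as red points with exact 95% counting intervals (231 against 601 cells). Open diamonds are the median of at least 2 other classes with enough of the gene, so classes in which it was low are left out. Dlc1 is an upper bound, Ccr2 lies at 1.00 with its diamond at -0.26, and Hspa1a lies at 1.57 with its diamond at 1.69.

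The resident macrophage list, whose members include C1q genes and other markers that define the class, had a median log2 ratio of -0.22 over 16 of 17 members, at percentile 0.09 of matched random lists, and -0.46 without doublet removal. None was 1.5 times higher and 1, Adgre1, was that much lower; Mrc1, the mannose receptor gene, stood at -0.53 and Cd63 at -0.42. The list of phagocytosis and efferocytosis genes had a median of -0.40 (11 of 15 members, percentile 0.34), with 4 members at least 1.5 times lower and none higher. Only 4 of the 11 could be set against other classes, and their median relative to those was 0.085. The lower members were Stab1, Gas6 (-2.10, -3.28 to -1.1), the scavenger receptor gene Msr1 (-0.75, -1.42 to -0.12) and the fatty acid receptor gene Cd36 (-0.61, -0.81 to -0.42). Msr1 stood at 0.00 without doublet removal. Gas6 stood at 9.53% of its level in thick limb cells and at -4.87 in T cell-like cells, and could be free RNA. As it was the only measured member of the long-lived tissue macrophage list, that list was not assessed. Complement genes had a median of -0.26 (6 of 10 members, percentile 1.64), or -0.47 without doublet removal, with the anaphylatoxin receptor gene C5ar1 at -1.36 (-1.66 to -1.08). In the same list C3ar1 stood at -0.27 and C1qc at -0.25.

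The recruited or monocyte-derived list had a median of 0.54 over 10 of 14 members (percentile 100), with 5 at least 1.5 times higher and 2 lower. The higher members were Ccr2, Napsa (1.02, 0.71 to 1.33), S100a4 (1.11, 0.79 to 1.44), Ms4a4c (1.18, 0.83 to 1.54) and S100a6 (1.38, 1.11 to 1.64). The monocyte genes Chil3 (-2.09, -3.60 to -0.87) and Ly6c2 (-0.71, -1.42 to -0.05) were lower, but stood at 1.07 and 1.35 without doublet removal. All 10 members but Ccr2 were under 20% of their level in the highest class, and the median was -0.05 with a minimum of 20 summed UMIs and 1.07 without doublet removal.

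Inflammatory cytokine and NF-kB genes had a median of 0.79 (10 of 14 members, percentile 100), with 7 at least 1.5 times higher and none lower. Il1b stood at 1.41 (1.33 to 1.48), the chemokine genes Cxcl2 and Ccl2 at 1.06 and 1.02, and Nfkbia, a feedback inhibitor of NF-kB, at 0.96. The list was not set apart from the other classes, since its median relative to them was -0.11, and 4 members could be free RNA. The dissociation and heat-shock stress list had a median of 0.27 (15 of 15 members, percentile 99.9), with 6 at least 1.5 times higher and 1 lower. Its highest member was the immediate early gene Ier3 (2.21, 1.91 to 2.51). Of the 15 members 2 could be free RNA, and Ier3 did not meet the rule for genes named by size. Genes of antigen presentation by MHC class II had a median of -0.13 (9 of 10 members, percentile 9.18), with none 1.5 times higher or lower. Cd86, a costimulatory ligand gene, stood at -0.51, Cd74 at -0.26, H2-Aa at -0.20 and the class II regulator gene Ciita at 0.44. Type I interferon response genes had a median of -0.17 (15 of 16 members, percentile 13.8) that was 0.06 without doublet removal. Ifit3 (-1.26, -1.76 to -0.78) and Ifit1 (-0.85) were lower, and Cxcl10 (0.89, 0.51 to 1.27) and Irf7 (0.56) were higher.

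The share of macrophage-like cells with a transcript was compared after each cell was thinned to 2000 UMIs. Ccr2 was found in 35.7% of 597 control cells (31.8 to 39.7%), 72.7% of 231 anti-CSF1R cells (66.5 to 78.4%) and 67.2% of 1145 CD11b-sorted anti-CSF1R cells (64.4 to 70.0%). T cell-like cells, some of which express Ccr2, gave 15.5%, 13.5% and 4.82%. Stab1 was found in 20.1%, 3.03% and 6.11% of macrophage-like cells, and in at most 0.183% of T cell-like cells. The chemokine gene Pf4, chosen after its values were seen, was found in 20.9%, 8.23% and 8.38%, with at most 0.137% in T cell-like cells. Csf1r was found in 79.2%, 69.7% and 76.9%, Adgre1 in 59.1%, 47.6% and 54.2%, and Cx3cr1 in 76.5%, 65.4% and 76.1%. Before thinning, macrophage-like cells had medians of 4985, 5929 and 5300 UMIs and T cell-like cells 5567, 5877 and 3997. No UMI of Cd163, Lyve1, Timd4 or Il34 was seen in macrophage-like cells of the unsorted libraries, which allows a UMI in up to 0.499% of control cells and 1.30% of anti-CSF1R cells. In the CD11b-sorted library Cd163 was found in 0.426% and Timd4 in 0.0853% of 1173 cells before thinning. Csf1 gave 16 control and 4 anti-CSF1R UMIs (log2 ratio -0.95, -2.99 to 0.69), and Itgam, which encodes CD11b, had a log2 ratio of 0.04 (-0.38 to 0.45).

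**Figure D3:**
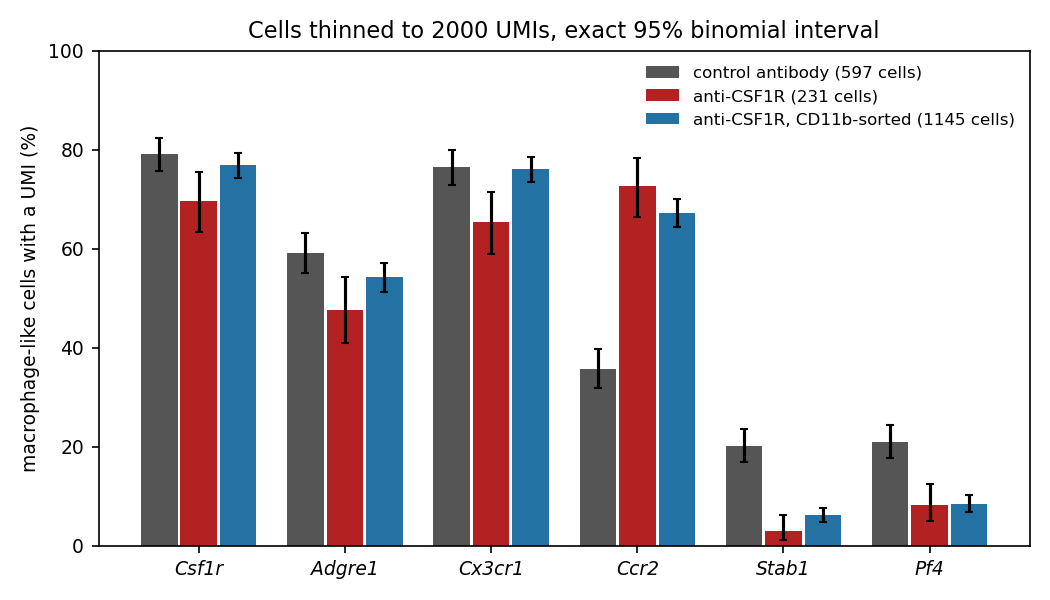
Percent of macrophage-like cells with at least 1 UMI of each gene after thinning to 2000 UMIs (bars from 0, with exact 95% binomial intervals), in the control (597 cells), anti-CSF1R (231 cells) and CD11b-sorted anti-CSF1R (1145 cells) libraries. Ccr2 was found in 35.7%, 72.7% and 67.2% of cells, and Stab1 in 20.1%, 3.03% and 6.11%.

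Other cell classes were compared to see whether expression differed beyond the macrophages. Transcripts of inducible heat-shock genes were higher in the anti-CSF1R library in lymphoid and myeloid classes alike. Hspa1a plus Hspa1b, inducible HSP70 genes, were 7.52 times as high in T cell-like cells (778 against 103 CPM), 7.40 times in B cell-like cells, 6.38 times in natural killer cell-like cells, 6.21 times in innate lymphoid cell-like cells, 3.77 times in type 2 dendritic cell-like cells and 2.78 times in monocyte-like cells. Macrophage-like cells had the highest level, 5148 against 1684 CPM (3.06 times). The transcriptional repressor gene Crem and the coregulator gene Ifrd1 were among the 5 highest in monocyte-like, B cell-like, T cell-like and natural killer cell-like cells, with log2 ratios of 1.53 to 2.65. Gstp1, a glutathione transferase gene, was the lowest gene in each of the 6 classes, with log2 ratios from -2.43 to -1.98. In macrophage-like cells, however, Gstp1 was far higher in the CD11b-sorted than in the unsorted anti-CSF1R library. The gene tables of those libraries differ, so a lower level of Gstp1 was not shown for both anti-CSF1R libraries.

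**Figure D4:**
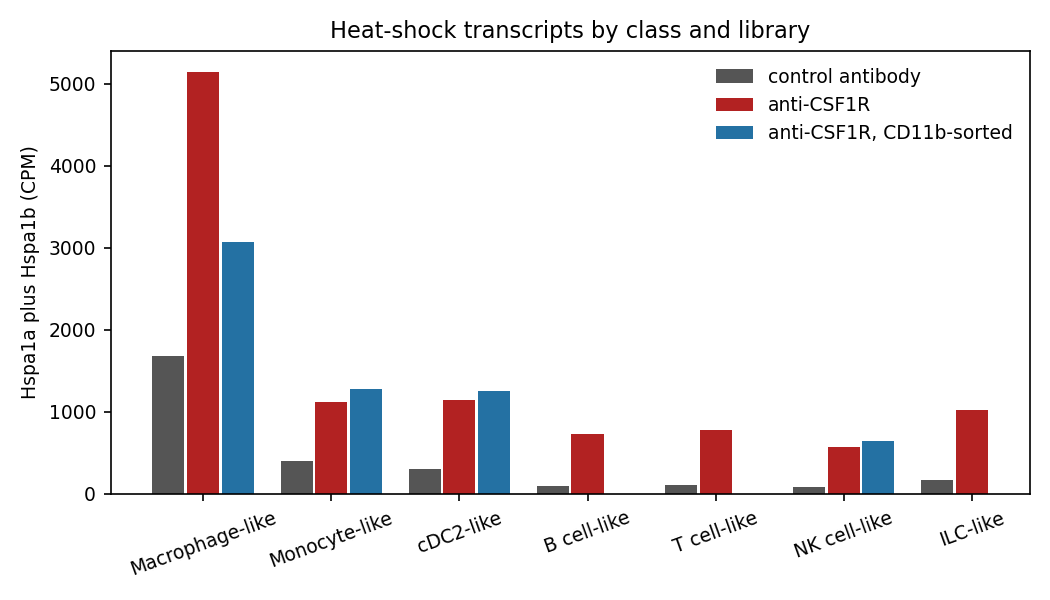
Summed CPM of Hspa1a and Hspa1b (linear axis from 0) by cell class in the control, anti-CSF1R and CD11b-sorted anti-CSF1R libraries, each bar 1 library; no bar is drawn where the sorted library had under 100 cells of a class. Every class drawn was lowest in the control library, with 1684 against 5148 and 3077 CPM in macrophage-like cells.

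Monocyte-like cells (860 anti-CSF1R and 451 control cells) showed higher Crem (log2 ratio 2.65, 2.09 to 3.26), Ifrd1 (2.36), the Notch feedback gene Nrarp (1.87), the activation marker gene Cd83 (1.77) and the survival gene Bcl2a1a (1.67). Chil3, a chitinase-like gene of classical monocytes, was lower (-1.91, -1.95 to -1.86), as were Gstp1 (-2.19), the kinase gene Dyrk3 (-1.80) and the histone gene Hist1h3a (-1.60). Ccr2 stood at -0.51 (-0.56 to -0.45) and Itgam at -0.24. The class was made up differently: the cluster led by Lyz2 and Chil3 held 71.4% of its control and 60.5% of its anti-CSF1R cells, and the one led by Ear2 and Ace 25.1% and 35.9%. Within these clusters Chil3 stood at -1.80 and -1.75 and Ccr2 at -0.33 (-0.39 to -0.28) and -0.83 (-1.06 to -0.60). Inflammatory genes had a median of 0.82 (12 of 14 measured, percentile 100), with 7 at least 1.5 times higher and none lower, led by Il6 (2.83, 1.73 to 4.19), Il1b (1.97), the prostaglandin synthase gene Ptgs2 (1.49) and Cxcl2 (1.31). Of the 12, 9 had under 20% of the level of the highest class and could be free RNA. Interferon response genes had a median of 0.19 (percentile 99.8), with the chemokine gene Cxcl10 at 1.27, and the stress list 0.14. The interferon median was 0.062 without doublet removal and 0.29 with median of ratios scaling, which gave 0.24 for the stress list. MHC class II genes had a median of 0.34 (percentile 100), with H2-Eb1 at 0.86, H2-Ab1 at 0.59 and H2-Aa at 0.55. This median was 0.01 without doublet removal, H2-Aa stood at -0.03, and 6 of 10 members could be free RNA.

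Type 2 dendritic cell-like cells (187 and 132 cells) included cells that were named type 1 at resolution 2, 79 in the anti-CSF1R and 47 in the control library, so the class is mixed. It had the orphan nuclear receptor gene Nr4a3 (2.33, 1.56 to 3.18), Ccl2 (2.13), Cd83 (2.02), Hspa1a (2.0) and Nr4a2 (1.89) as the highest genes. Among the lowest were Gstp1 (-1.98), Hivep2 (-1.56), the calcium pump gene Atp2b4 (-1.53) and the fucosyltransferase gene Fut7 (-1.48). Inflammatory genes had a median of 0.73 (9 of 14 measured, percentile 100) with Il1b at 2.48 and Ccl4 at 1.45, and 6 of the 9 could be free RNA. The stress list had a median of 0.29 (percentile 100), and the interferon list 0.09 (percentile 86.2).

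In lymphoid classes the stress list had medians of 0.28 in B cell-like, 0.31 in T cell-like, 0.39 in natural killer cell-like and 0.44 in innate lymphoid cell-like cells, each at percentile 100. Of its measured members 5 of 14, 6 of 15, 6 of 15 and 7 of 14 were at least 1.5 times higher, and 2, 1, 2 and 0 that much lower. T cell-like cells (2977 and 2254 cells) had Nr4a3 (1.89), Crem (1.83), the immediate early gene Ier5l (1.59), Ifrd1 (1.53) and the small GTPase gene Rrad (1.5) as highest genes, and Gstp1, Impact (-1.35), Leng8 (-1.24) and C2cd5 (-1.03) among the lowest. Their interferon list had a median of 0.32 (15 of 16 measured, percentile 100), led by Cxcl10 (1.86, 1.70 to 2.03), the ubiquitin-like modifier gene Isg15 (0.98, 0.86 to 1.1), Rsad2 (0.72) and Ifit3 (0.70). The T cell-like cluster led by these genes held 59 anti-CSF1R and 28 control cells. B cell-like cells (2682 and 1826 cells) were led by Crem (2.41), Nr4a1 (1.90), Ifrd1 (1.76), the sorting protein gene Vps37b (1.56) and the urokinase receptor gene Plaur (1.55), with Gstp1 (-2.14), Impact (-1.34), B3gnt8 (-1.18) and Scml4 (-1.07) among the lowest. Their interferon median was 0.14, with Oasl2 at -0.91 and Isg15 at 0.50.

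Natural killer cell-like cells (1409 and 811 cells) had Crem (2.21), Nr4a3 (2.07), Ifrd1 (1.97), Nr4a2 (1.62) and Ier5l (1.55) highest and Gstp1 (-2.40), Impact (-1.51), Rfx1 (-1.21) and the immediate early gene Fosb (-1.12) among the lowest. Innate lymphoid cell-like cells (201 and 135 cells) had Nr4a3 (3.09), Crem (3.04), Gadd45b (2.85), Hspa1b (2.38) and Rrad (2.37) highest and Gstp1 (-2.43), Gigyf1 (-1.57), Slc43a2 (-1.54) and Tasor (-1.45) among the lowest. The interferon median was 0.24 in natural killer cell-like and 0.39 in innate lymphoid cell-like cells. Of the measured interferon genes, 8 of 11 in B cell-like, 6 of 10 in natural killer cell-like and 5 of 15 in T cell-like cells could be free RNA. Inflammatory genes had medians of 0.49 in natural killer cell-like, 0.00 in B cell-like and -0.02 in T cell-like cells, and 1.57 in innate lymphoid cell-like cells, where 3 genes were measured (Nfkbia, Cxcl2 and Tnfaip3) and the median was 0.57 without doublet removal. Of the measured inflammatory genes, 6 of 8 in natural killer cell-like, 7 of 7 in B cell-like and 7 of 9 in T cell-like cells could be free RNA, as could 9 of 15 stress genes in natural killer cell-like and T cell-like cells and 8 of 14 in B cell-like cells. Median of ratios scaling moved all log2 ratios by 0.22 in T cell-like, 0.18 in B cell-like, 0.15 in natural killer cell-like, 0.13 in innate lymphoid cell-like, 0.10 in dendritic and 0.10 in monocyte-like cells. The all-gene medians of these classes were -0.23, -0.18, -0.14, -0.09, -0.08 and -0.08.

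The CD11b-sorted library shows which cells the gate held, and its shares were set by the sort. Natural killer cell-like cells were its largest class with 34.0% of kept cells (33.0 to 35.1%, 2671 cells). Monocyte-like cells followed with 20.8% (19.9 to 21.7%), neutrophil-like cells with 19.7% (18.8 to 20.6%) and macrophage-like cells with 14.9% (14.2 to 15.7%). Neutrophil-like cells numbered 1547 here and 38 in the unsorted anti-CSF1R library. Type 2 dendritic cell-like cells made up 3.31%, B cell-like cells 1.16% and T cell-like cells 1.08%. No innate lymphoid cell-like cell was found among 7851, which allows a share of up to 0.0382%. Unnamed clusters held 3.55%.

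The sorted and unsorted anti-CSF1R libraries were compared to see how far sorted cells stand for unsorted ones. In macrophage-like cells (1173 sorted and 231 unsorted), Itgam, the gene of the sorted antigen, was higher in the sorted library (log2 ratio 0.72, 0.37 to 1.08). Csf1r (0.30), Adgre1 (0.28), Cx3cr1 (0.10) and Ccr2 (-0.12) were within 1.5 times. Resident macrophage genes had a median of 0.01 (16 of 17 measured, percentile 52.2). Inflammatory genes had a median of -0.48 (6 of 12 could be free RNA) and stress genes one of -0.51, both at percentile 0, with Il1b at -1.26 (-1.33 to -1.20), Cxcl2 at -0.97, Hsp90aa1 at -0.90 and Hspa1a at -0.82. Csf1 was higher (3.70, 2.32 to 5.58), but stood at 1.09 (-0.38 to 3.03) without a cluster of 19 sorted cells led by Ccl12, Csrp3 and C1qa. This cluster had 212 of the 252 Csf1 UMIs and a median of 9998 UMIs per cell, against 5263 in the other 1154 cells. The basophil gene Cd200r3 was found in 18 of its 19 cells and in 1 of the 1154. It stood at 393 CPM in this cluster, 0.141 in the 1154 cells and 1002 in 33 sorted basophil-like or mast cell-like cells. C1qa stood at 2813, 6063 and 23.3 CPM. Doublets with basophils would give such levels between those of both classes, and they are not excluded. Recruited list genes had a median of 0.44 (13 of 14 measured, percentile 99.9), of which 11 could be free RNA, and the median was -0.23 without doublet removal; Fn1 (2.29), Plac8 (2.07), F13a1 (1.97) and Chil3 (1.74) then also turned to negative values.

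In monocyte-like cells (1630 sorted and 860 unsorted) Itgam (0.01, -0.06 to 0.08) and Ccr2 (0.02, -0.02 to 0.06) were alike. Stress genes had a median of 0.30 (percentile 100), led by Jun (1.17), Atf3 (0.89) and Dusp1 (0.79), and inflammatory genes one of -0.18 (percentile 0.21, 8 of 12 could be free RNA), with Il6 at -1.96, Il1b at -1.37 and Ccl3 at 1.29. The largest ratios between these libraries, whose gene tables differ, were in macrophage-like cells those of Taf6l (4.55), Amd2 (at least 3.78), Coro1b (3.59), Gstp1 (3.52) and Chtf8 (3.41) on the higher side, and Fdx2 (-8.19), Rnasek (-7.85), Gng10 (-6.10), Atp6v0c (-6.01) and Nme2 (-5.65) on the lower. In monocyte-like cells Ptp4a1 (5.61), Taf6l (4.48), Coro1b (3.92), Apoc2 (-8.44) and Rnasek (-7.06) were among the largest. Taf6l, Coro1b and Rnasek thus recurred in both classes. How far the unlike gene tables gave these ratios was not tested, so they are not read as differences in expression. The neutrophil alarmin transcripts S100a8 and S100a9 made up 344 CPM in T cell-like cells of the sorted library and 11.4 in those of the unsorted one.

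Sex-linked transcripts were compared because the labels give no sex. Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty) made up 142 CPM in the control, 141 in the anti-CSF1R and 104 in the CD11b-sorted library. Xist and Tsix together made up 0.286, 0.200 and 0.0565 CPM. Y-linked transcripts were thus present and Xist and Tsix nearly absent in all 3 libraries. These values give no sign that the libraries differed in the sex of the mice. Male-biased proximal tubule genes made up 2259 CPM in the control library, which held most tubule cells, and 37.3 and 191 in the other libraries, and female-biased ones 17.7, 1.24 and 6.27.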

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

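No test was run in this part. Endothelial cell-like cells made up 1.87% of kept cells in the anti-CSF1R library (1.60 to 2.17%, 170 cells), above the 0.0679% of the control library (5 cells) and the 0.0637% of the CD11b-sorted library (5 cells). The ratio to the control library depended on the doublet setting, as it was 27.6 with removal at the nominal rate, 5.31 without removal and 4.78 with the automatic threshold. Cells were clustered anew under each setting, and the cause of the difference was not tested. These cells stood out because they are not immune cells and lie outside every expression comparison, for which the control library held too few.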

How the results depend on the processing

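The main cell shares, list medians and named genes of the unsorted libraries, the shares of the main classes of the sorted library, and the expression of its macrophage-like and monocyte-like cells were recomputed with 1 choice altered at a time. The shares of plasma cell-like, basophil-like or mast cell-like and plasmacytoid dendritic cell-like cells, shares of cells with a UMI, summed CPM of a few genes, and expression in natural killer and dendritic cell-like cells of the sorted library were not. Of the values that answer a comparison, 218 stayed within their counting interval, 65 moved out of it and 9 reversed, that is, lay on the other side of no difference from an interval that excluded it. Of the other values, which were those of single genes and counts of genes chosen again, 935, 172 and 16 did so, a count moving if the main count was over 1.5 times as large. No paired analysis was possible because each group was 1 library, and leaving out a replicate was not possible for the same reason. The settings added after seeing the data were the low-UMI cluster, the values relative to other classes or without possible free RNA, and those for the other shares and for sorted against unsorted cells. Depth limits what could be measured: the macrophage-like comparison rests on 231 anti-CSF1R cells with 1511070 UMIs, and the innate lymphoid one on 201 with 1123293. The values below moved or reversed, and except where stated the cause was not tested.

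Without doublet removal the macrophage-like ratio of shares was 0.385 of all kept and 0.348 of immune cells, and the endothelial one 5.31 (4.78 with the automatic threshold). The monocyte-like ratio was 1.24 with at least 1000 UMIs and 1.18 with libraries clustered apart, which gave 0.785 for type 2 dendritic cell-like cells, as type 1 cells were then split off in the anti-CSF1R library and not in the control library. A mitochondrial maximum of 10% gave 1.04 for T cell-like, 1.1 for natural killer cell-like and 0.0584 for thick limb cells. The podocyte-like ratio reversed to 1.22 at resolution 2, 1.22 at a mitochondrial maximum of 50%, 1.71 without doublet removal, 1.62 with the automatic threshold and 6.27 with libraries clustered apart. In the CD11b-sorted library the macrophage-like share was 14.0% at resolution 2, 16.5% without doublet removal and 18.3% with the low-UMI cluster. The monocyte-like share was 22.0% at a mitochondrial maximum of 10%, 22.1% with at least 1000 UMIs and 19.6% without doublet removal, which gave 21.1% neutrophil-like and 32.1% natural killer cell-like cells.

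In macrophage-like cells, anti-CSF1R against control antibody, leaving doublets in gave medians of -0.46 for resident, 1.07 for recruited, -0.47 for complement, -0.21 for MHC class II and 0.058 (reversed) for interferon genes, and reversed Chil3 (1.07), Ly6c2 (1.35) and Msr1 (0.0012). The recruited median, from 10 members, was 1.03 with thinned cells and 1.00 with at least 200 summed UMIs, each from 3 members, and -0.048 (reversed) with at least 20, from 12. The inflammatory median was 0.99 with thinned cells (10 members) and 0.96 with at least 200 UMIs (7 members). Relative to the other classes the medians were 0.74 for recruited, -0.11 (reversed) for inflammatory, 0.12 for stress, -0.14 for MHC class II and -0.44 for interferon genes.

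Median of ratios scaling gave, in monocyte-like cells, stress 0.24, interferon 0.29, MHC class II 0.44 and Csf1r 0.013 (reversed). It gave stress 0.39 in dendritic cells, inflammatory 0.18, stress 0.46 and interferon 0.32 in B cell-like cells, and inflammatory 0.20, stress 0.54 and interferon 0.54 in T cell-like cells. It gave inflammatory 0.64, stress 0.54 and Ly6c2 0.052 (reversed) in natural killer cell-like cells and inflammatory 1.70 and stress 0.58 in innate lymphoid cells. The mean of CPM per cell gave MHC class II 0.20 in monocyte-like cells, and inflammatory 0.18 and interferon 0.19 in T cell-like cells. Without doublet removal monocyte-like cells had interferon 0.062, MHC class II 0.0069, Cd74 -0.076 and H2-Aa -0.027 (both reversed), dendritic cells inflammatory 0.94, T cell-like cells inflammatory 0.18 and innate lymphoid cells inflammatory 0.57.

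In macrophage-like cells, CD11b-sorted against unsorted, the mean of CPM per cell gave resident 0.054, recruited 0.32, inflammatory -0.62 and stress -0.60. Thinned cells gave resident 0.049, recruited 0.31 (6 members against 13) and inflammatory -0.88 (8 against 12), and libraries clustered apart 0.046, 0.30 and -0.59. Without doublet removal they were resident 0.21, recruited -0.23 (reversed) and stress -0.23, with Cd81 0.077, Chil3 -0.82, F13a1 -0.057, Fn1 -0.54, Il6 -0.24, Ly6c2 -0.83 and Plac8 -0.23 reversed. Thinning also reversed Cd81 (0.0070) and Il6 (-0.093), and monocyte-like cells had stress 0.35 without doublet removal.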

Other observations

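The values in this first paragraph were read after the comparisons above and were not recomputed under other settings. Natural killer cell-like cells of the CD11b-sorted library (2671 cells) had more Itgam than those of the unsorted anti-CSF1R library (1409 cells), with a log2 ratio of 1.52 (1.41 to 1.64). Ly6c2 (0.80, 0.75 to 0.85) and the fractalkine receptor gene Cx3cr1 (1.78, 1.60 to 1.97) were also higher, although Cx3cr1 reached only 14.5% of its level in macrophage-like cells, and Ccr2 was lower (-0.74, -0.83 to -0.64). The class was made up differently, with 97.4% of its sorted and 63.2% of its unsorted cells in the cluster led by Gzma and Klra4. Within that cluster the log2 ratios were 0.89 (0.77 to 1.01) for Itgam, 0.48 for Ly6c2, 1.23 for Cx3cr1 and -0.77 for Ccr2. A cycling cluster of mixed identity, led by Pclaf, Top2a and Birc5 and with 6 T cell markers detected, held 30 control, 88 anti-CSF1R and 14 CD11b-sorted cells. Interferon-induced genes led a monocyte-like cluster of 16, 31 and 52 cells.

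All tests in the next 3 paragraphs were chosen after the results they bear on had been seen. The macrophage-like share of immune cells in the anti-CSF1R library was 0.284 of that in the control library. A rise of some of the 6 other classes with at least 100 cells would leave macrophage-like cells per cell of the rest near the control value, but the highest of these 6 ratios was 0.291; a rise shared by all 6 stays open, since smaller classes gave 0.314 to 0.730, the last from 30 and 57 cells. Counting the low-UMI cluster with macrophage markers as macrophage-like gave 0.282, so loss to that cluster is argued against too. Over all kept cells, with no cell names, C1qa, C1qb and C1qc were 463 against 1222 CPM, a ratio of 0.379. This argues against loss to other names of cells that kept these genes. It cannot show whether macrophages low in these genes were named otherwise, which stays open. A difference in cell recovery stays open: free tubule RNA in T cell-like cells was 526 times as high in the control library, and with 1 library per group recovery and the antibody cannot be told apart.

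Hspa1a plus Hspa1b were higher in all 7 compared classes of the anti-CSF1R library. Free RNA spread over all droplets would put a UMI in most cells, but the share of cells with one was at most 0.621 of that of an even spread in the 6 classes other than macrophage-like, which argues against free RNA as the whole cause. This test took the place of a first one on added CPM, which in lymphoid classes was alike at 478 to 860 CPM, and the next one first asked each class to be as high as in the unsorted library, which macrophage-like cells were not. Handling of the unsorted anti-CSF1R library alone is argued against for the 4 classes with at least 100 sorted cells, since the CD11b-sorted library stood at 1.83 times control or more in each (median 3.65) and above the unsorted library in 3, while a part in macrophage-like cells stays open, where it stood at 0.598 of the unsorted library. An effect of the antibody and handling of both anti-CSF1R libraries, shared or separate, could each give the ratios seen, of which the lowest was 2.78, and they cannot be told apart without replicate libraries.

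Ccr2, Napsa, S100a4, S100a6 and Ms4a4c were at least 1.5 times higher in macrophage-like cells of the anti-CSF1R library. Admixture of monocyte-like or dendritic cells or doublets was set at a share estimated from the leading genes of 3 source clusters. It would bring 38.3% of the added Ccr2 CPM but at least 141% of that of each other gene. This share is too high, since it would bring 150 CPM of Napsa, 448 of S100a4 and 466 of S100a6. The class held only 114, 111 and 175 CPM of these in the anti-CSF1R library. For Ccr2 and Ms4a4c it would bring less than the class held, 149 of 778 and 72.4 of 92.0 CPM. The percentages are thus overestimates, and admixture is argued against as the whole cause for Ccr2. For the other 4 genes they cannot decide, and admixture stays open. Free RNA is argued against for Ccr2, since B cell-like cells of the same library held 6.27 CPM, or 1.62% of the added CPM; a first form of these tests took all 5 genes together and gave medians of 260% for admixture and 89.6% for free RNA, before Ccr2 was found to stand apart. A hypothesis is that more of the macrophage-like cells present after the antibody may stem from Ccr2-expressing monocytes, and Ccr2 was found in 67.2% of macrophage-like cells of the CD11b-sorted and 72.7% of the unsorted anti-CSF1R library against 35.7% in the control library, after thinning to 2000 UMIs. More Ccr2 in resident cells would give the same shares. So would a larger loss of cells without Ccr2, as macrophage-like cells were 2.65% of immune cells against 9.32% in the control library. Both anti-CSF1R libraries may come from the same mice, and cell origin was not traced, so the hypothesis stays open.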
